A study of Homo sapiens with 16 samples.

How the data were processed

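Total RNA of LNCaP-1F5 cells was hybridized as biotinylated cRNA to 16 Illumina HumanHT-12 arrays, 8 of version 3 for the DHT set and 8 of the following version for the DEX set. Groups and replicate numbers were taken from the sample titles: 4 groups of 2 arrays per set. Scanner columns were assigned to samples by the array position that each label states. These labels give the 8 arrays of a set 1 chip number, with replicates 1 and 2 alternating in position. Per the file headers, the deposited scanner files hold the mean bead signal of each probe as intensity on the linear scale, exported from BeadStudio with no background removed and no normalization between arrays. Per the same file headers, a detection p-value of each probe against the negative control beads of its array was deposited beside it. In 353 of 390424 such cells of the DHT set and 273 of 377848 of the DEX set, a p of 1 was written with a shifted separator and was read as 1. The authors also deposited a table of intensity values per set. From the values themselves, that table was background-subtracted (33.4% and 29.2% of values below 0) and quantile normalized across the 8 arrays, on the linear scale, by a method the labels do not state.

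The scanner files name probes by address and the authors' tables by probe identifier, so the rows were joined by their ranks on the 8 arrays of a set. All 48794 and 47231 rows of the authors' tables were joined 1 to 1, leaving 9 and 0 scanner rows; the next nearest row was at least 14.6 and 19.1 times as far. Of 39417 identifiers in both sets, 37888 (96.1%) led to the same address. The join was tested on simulated data and recovered 20000 of 20000 rows. Gene symbols came from the deposited probe annotation (28090 and 30113 probes with 1 symbol, 13 and 8 with several, 20691 and 17110 with none), and 31 and 32 probes took an updated symbol from a RefSeq gene table. Probe coordinates were not analysed here.

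Scanner signals were background-corrected against negative controls inferred from the detection p, quantile normalized within each set and put on the log2 scale with an offset of 16 (limma neqc). Probes with a detection p under 0.01 on at least 2 of the 8 arrays were kept (13094 and 18391), and each gene was represented by its probe with 1 symbol and the highest mean, which gave 9027 genes in the DHT set and 10993 in the DEX set; 1807 and 3860 kept probes had no single symbol. Where other probes of a named gene passed the filter they were checked, and disagreement in sign is stated. A model of 4 group means was fitted to the 8 arrays of a set with limma, with a variance trend on intensity and 4 residual degrees of freedom, and p-values were adjusted by Benjamini and Hochberg over all genes of a comparison; a gene was called at an adjusted p under 0.05. Both responses to hormone, both effects of depletion and the interaction were tested in each set, two-sided. Where a group was not detected, the fold is a lower bound set by the detection limit of its arrays.

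Before the data were examined, 20 gene lists were fixed: androgen-induced, androgen-repressed, glucocorticoid-induced, androgen metabolism, polyamine, cholesterol and fatty acid synthesis, G1/S, G2/M, p53 target, ER chaperone and unfolded protein response, glycolysis, interferon response, metallothionein, luminal epithelial, basal epithelial, mesenchymal, neuroendocrine and neuronal genes, blood and endothelial cell markers, steroid receptors and partner factors, and common control genes. Lists with at least 3 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison (18 in the DHT set, 19 in the DEX set), and again with an estimated correlation. Also fixed then were the comparisons, the alternatives and the rule for named genes: FOXA1, NR3C1 and a gene that is not reported here; the 8 largest called increases and the 8 largest called decreases of each response and of depletion without hormone, where the groups do not overlap; and the 3 members with the largest moderated statistic of each list described. Genes without a symbol and Y-linked genes were left out. The 3 probes of NR3C1 were not detected often enough to be tested.

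Checks on simulated data drew 9027 and 10993 genes with the spread of each set. Of 100 genes given a change of 1 on the log2 scale, 31 were called in the DHT set and 32 in the DEX set, and of 100 given a change of 3, 86 and 80 (median estimates 1.03, 1.04, 2.99 and 2.97), with 9 and 7 unchanged genes called. A G2/M list raised by 1 was called in both (adjusted p = 5.43e-33 and 2.98e-09), with 0 of 17 and 0 of 18 other lists called. Simulated genes and arrays were drawn independently, with no difference shared by arrays of 1 replicate number. These checks therefore cannot tell whether the preset inter-gene correlation holds for the real arrays. Alternatives tried were another background correction (offset 50), none, median scaling, the authors' values floored at 16, no filter, detection on all 8 arrays, all probes, no variance trend, only the arrays compared, a minimum change of 1.5-fold, the replicate number as a block, and each array left out in turn. Of these only leaving out leaves a group with a lone array, which was then assumed to vary like the other groups. Part of any difference between replicate numbers then enters the comparison. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.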

Results

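Expression was measured in LNCaP-1F5, a human prostate cancer line derived from LNCaP that carries an introduced rat glucocorticoid receptor. According to the labels, parental cells and cells depleted of the pioneer factor FOXA1 by siRNA spent 3 days in stripped medium and then 24 hours with vehicle or hormone. The androgen dihydrotestosterone (DHT) was given at 100 nM in 1 set of 8 arrays, and the synthetic glucocorticoid dexamethasone (DEX) at 100 nM in the other set of 8 arrays. Each set holds 4 labelled groups of 2 arrays: vehicle parental, hormone parental, vehicle depleted and hormone depleted. In the DHT set, 11218 to 12886 of 48803 probes were detected per array (23.0% to 26.4%), and the mean scanner signal was 390.5 to 528.1. For the DEX set, which used the next version of the array, 15933 to 17168 of 47231 probes were detected (33.7% to 36.3%), and the mean signal was 597.4 to 683.1. Having 2 arrays per group limits the precision of every value. Levels were not compared between the sets, which were normalized separately.

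FOXA1 itself contradicted the labels in the DHT set, and in the DEX set it differed both by labelled depletion and by replicate number. In the DHT set, its log2 level was 13.54 and 13.61 on the arrays labelled vehicle parental and 13.57 and 13.68 on those labelled vehicle depleted. It was 12.24 and 12.25 on the arrays labelled DHT parental and 12.28 and 12.37 on those labelled DHT depleted, so FOXA1 followed the labelled hormone and not the labelled depletion. In the DEX set, FOXA1 was 13.36 and 12.09 on the arrays labelled vehicle parental, 13.37 and 12.17 on DEX parental, 12.65 and 10.84 on vehicle depleted, and 12.67 and 10.84 on DEX depleted, the arrays of replicate 1 first. Between arrays of the same replicate number it was lower on those labelled depleted, as the labels say, by 0.71 and 1.25 with vehicle and by 0.70 and 1.33 with DEX. The 2 arrays of each labelled group were nevertheless 1.20 to 1.83 apart. FKBP5, a gene induced by both androgens and glucocorticoids, differed by replicate number in the DHT set but by labelled depletion in the DEX set. In the DHT set it was 7.92 and 12.15 on the arrays labelled vehicle parental, and 8.21 and 13.16 on those labelled DHT parental. In the DEX set it was 9.35 and 9.21 on vehicle parental and 9.23 and 9.39 on DEX parental. There it was 13.89 and 13.88 on vehicle depleted, and 13.8 and 13.81 on DEX depleted. Across genes, 0 of 8 arrays in each set had the other array of its labelled group as its nearest array. The nearest array carried the same replicate number for 8 of 8 arrays in each set. In the DHT set it also shared the labelled hormone and differed in labelled depletion. In the DEX set it shared the labelled depletion and differed in labelled hormone. Arrays of the same number but other labelled hormone correlated at 0.9471 to 0.959 in the DHT set. Those of the same number but other labelled depletion correlated at 0.9396 to 0.9495 in the DEX set. Nearest arrays correlated across genes at Pearson r = 0.987 to 0.9887 in the DHT set and 0.9877 to 0.9917 in the DEX set, while arrays of the same labelled group correlated at 0.9557 to 0.9674 and 0.9573 to 0.966. Groups are therefore named below by their labels, as "arrays labelled DHT parental", and each direction given is a direction between labels. No array was moved to another group.

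**Figure D1:**
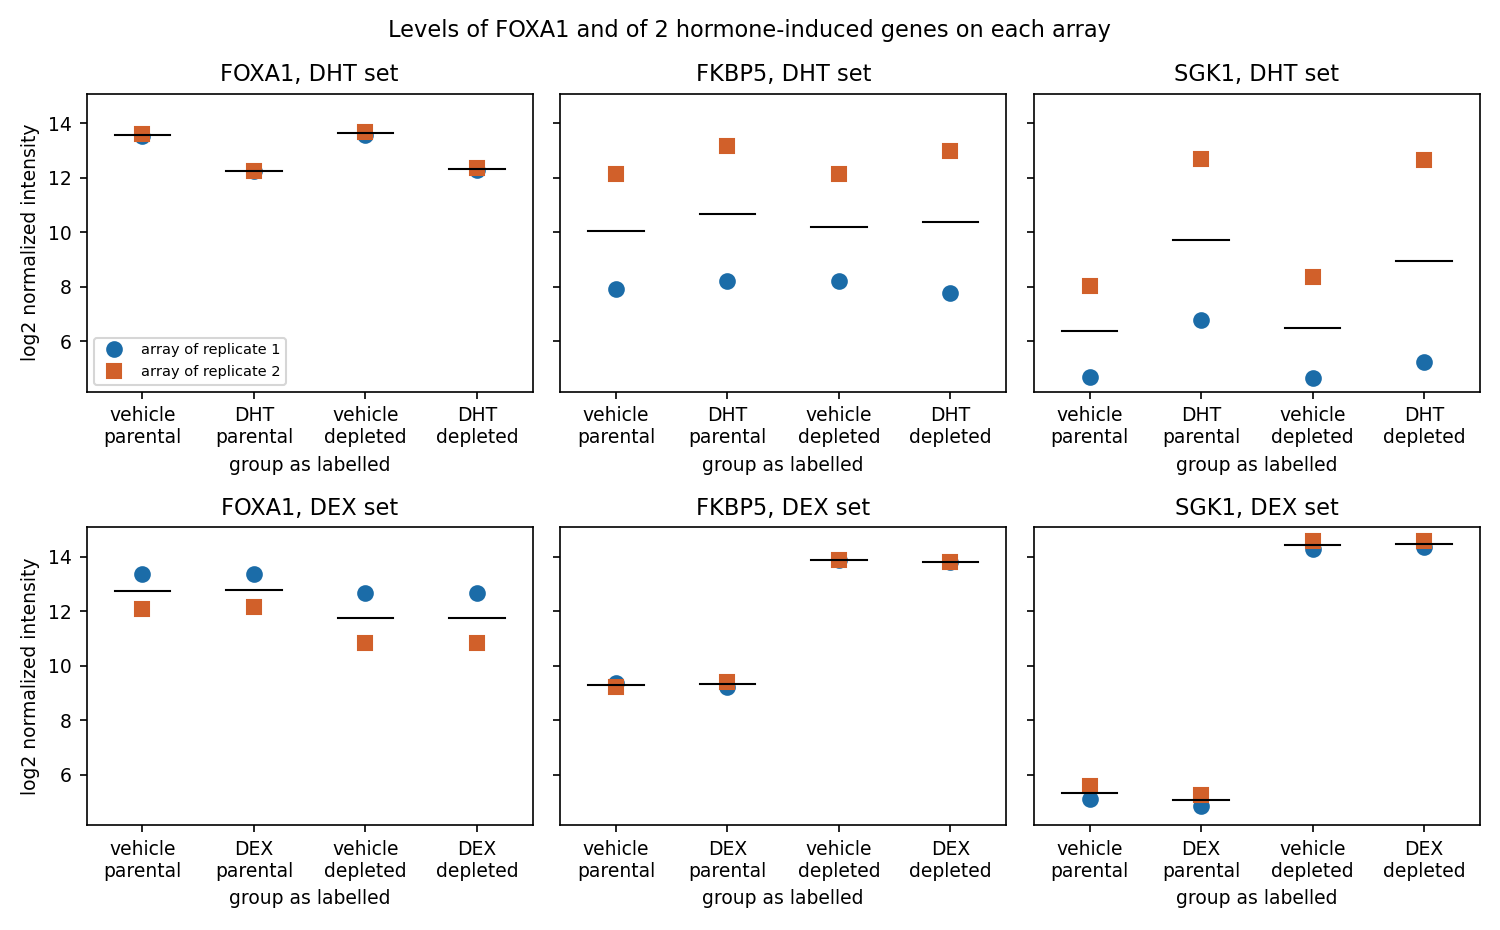
Log2 levels of FOXA1, FKBP5 and SGK1 on each of the 16 arrays, by labelled group (points, colour and shape giving the replicate number). FOXA1 lay at 12.24 to 12.37 on the 4 arrays labelled DHT and at 13.54 to 13.68 on the 4 labelled vehicle in the DHT set, while in the DEX set the arrays of 1 group differed from each other.

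**Figure D2:**
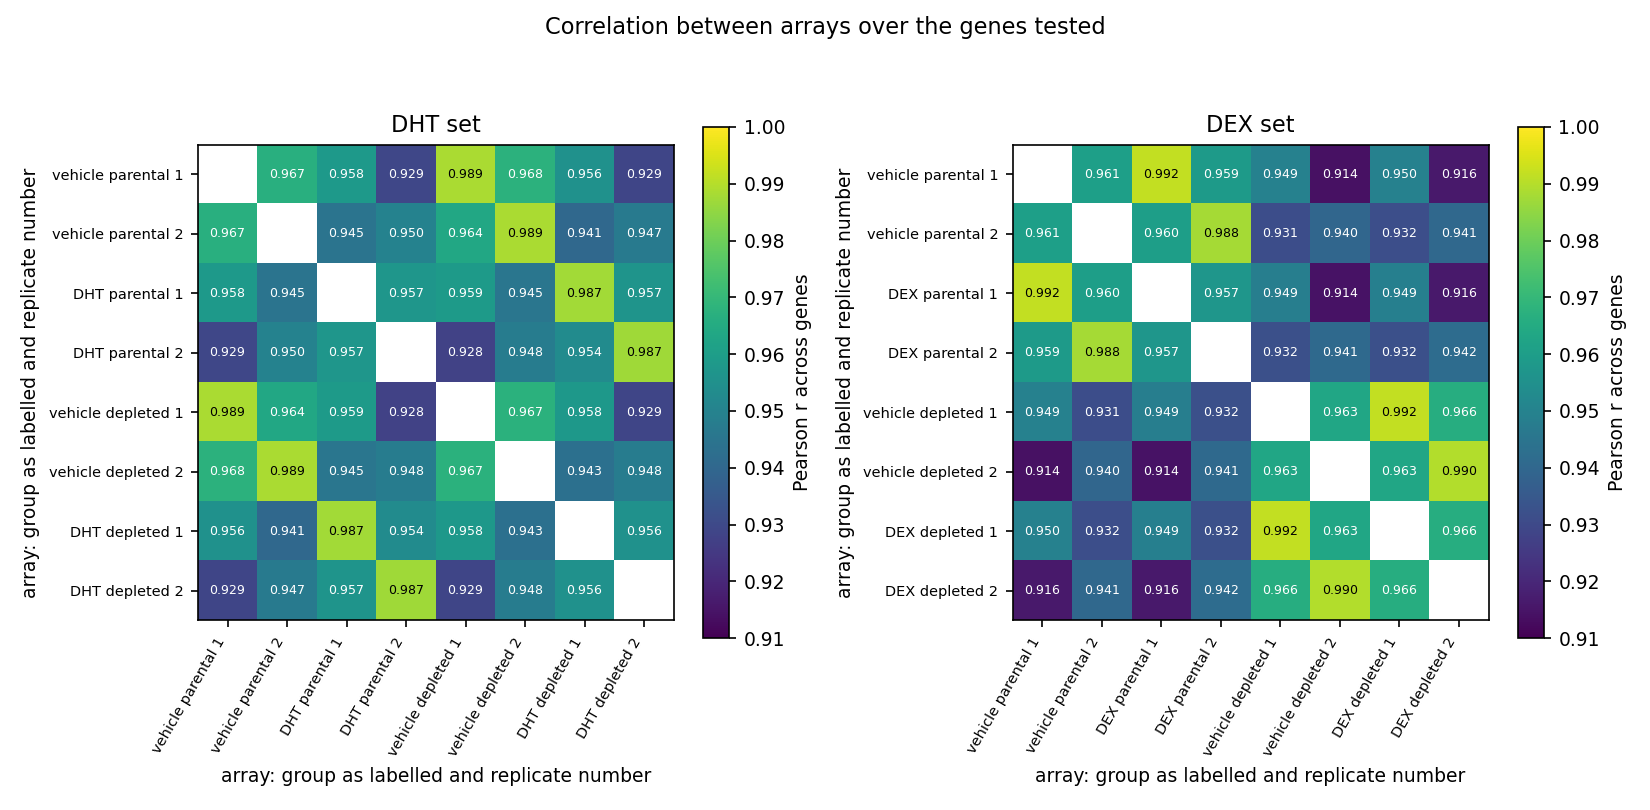
Pearson correlation across genes between every pair of the 8 arrays of each set (colour scale from 0.91 to 1). Each array correlated best, at 0.987 or more, with an array of the same replicate number from another labelled group. That array also shared the labelled hormone in the DHT set and the labelled depletion in the DEX set.

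The response of parental cells to DHT was the question of the arrays labelled DHT parental against those labelled vehicle parental. ENC1, an actin-binding protein, was higher by 5.15 ± 0.19 on the log2 scale (± SE, n = 2 arrays per group; adjusted p = 6.89e-05). Its level was 12.02 ± 0.14 against 6.87 ± 0.03 (mean ± SD). IGFBP3, which binds insulin-like growth factors, was higher by 5.62 ± 0.55 (adjusted p = 0.00676), S1PR3, a sphingosine 1-phosphate receptor, by 4.47 ± 0.43, and the matrix glycoprotein THBS1 by 4.10 ± 0.53. Not detected on the arrays labelled vehicle parental were SLPI, a secreted protease inhibitor (at least 29.0-fold higher), CA4, a carbonic anhydrase (at least 20.4-fold), the calcium-binding protein SCGN (at least 11.8-fold) and TLL2 (at least 10.4-fold). SPON2 fell by 2.43 ± 0.30 (adjusted p = 0.0171), HES6, a transcription factor of the HES family, by 2.39 ± 0.34, and the secreted peptide TFF3 by 2.29 ± 0.35, with RAP1GAP and TRIM68 lower by −1.83 ± 0.22 and −1.78 ± 0.16. AMHR2, SEMA6A and SLC45A2, undetected on the arrays labelled DHT parental, were at least 4.24-fold, 3.51-fold and 2.97-fold lower. FOXA1 differed by −1.33 ± 0.11 (adjusted p = 0.00519), a fall between arrays that the labels call parental throughout.

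The limma test over 9027 genes called 69 genes (38 higher and 31 lower on the arrays labelled DHT parental). At an unadjusted p under 0.05 there were 1189, where chance alone gives 451 for arrays that vary independently. This fit counts the difference between replicate numbers as spread between arrays. The same test called 341 higher and 408 lower with replicate number as a term. All 69 had groups that did not overlap, as did 43.3% of all genes. Without the vehicle parental array of replicate 1 the count was 19, without that of replicate 2 it was 18, and without the DHT parental arrays of replicates 1 and 2 it was 4 and 20. Of 22 genes called and named for this comparison, 9, 10, 3 and 11 passed without these arrays in the same order. ENC1, CA4 and SCGN passed without any 1 of the 4, and FOXA1 missed only without the DHT parental array of replicate 1 (adjusted p = 0.0519). Under at least 1 other setting the calls of HES6, TFF3, SEMA6A, SLC45A2, MCM7, GINS2 and UBE2C were lost, with adjusted p of 0.0504 to 0.0951.

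**Figure D3:**
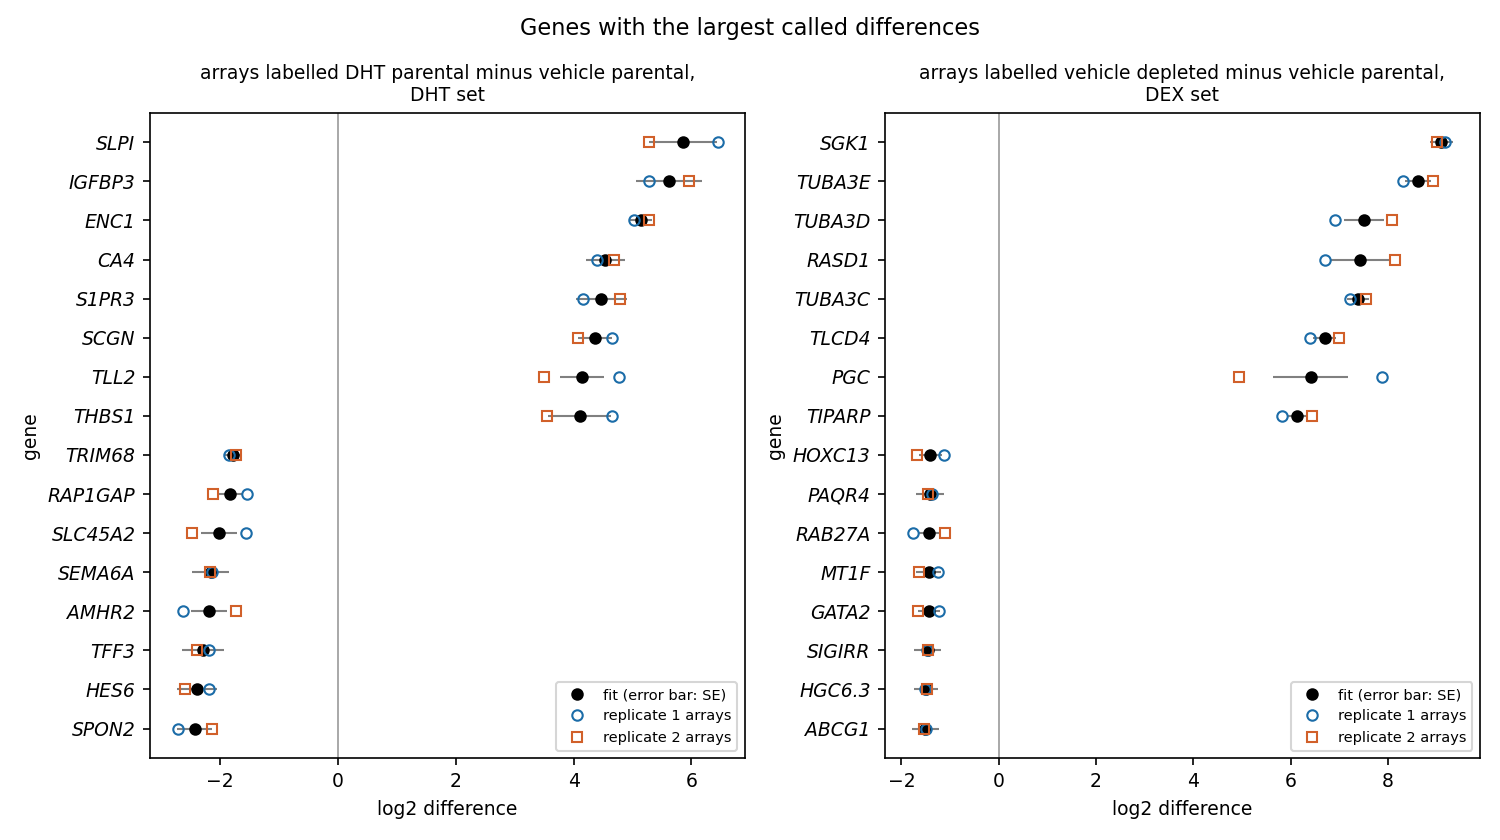
Log2 differences of the 16 genes with the largest called differences in each of 2 comparisons (black points with SE from the fit; open symbols, differences between arrays of the same replicate number). ENC1 stood 5.15 higher on arrays labelled DHT parental in the DHT set, and SGK1 9.09 higher on arrays labelled vehicle depleted in the DEX set.

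Cell cycle genes were lower as groups on the arrays labelled DHT parental. The G2/M list had a median of −0.95 over 25 measured genes (adjusted p = 4.43e-16, and 0.0227 with an estimated correlation). Of its members 2 fell over all genes tested and 21 adjusted over the list alone. TOP2A, the topoisomerase of mitotic chromosomes, differed by −1.31 ± 0.17 and UBE2C, a ubiquitin-conjugating enzyme of the anaphase pathway, by −1.09 ± 0.17, while CCNB2 at −0.95 ± 0.18 did not pass (with replicate number as a term, adjusted p = 0.00883). The G1/S list had a median of −1.05 over 23 genes (adjusted p = 8.18e-13), a call that was lost at adjusted p = 0.248 with an estimated correlation. Here 2 genes fell over all genes, the replication factors MCM7 (−1.26 ± 0.17) and GINS2 (−1.19 ± 0.19), and 17 adjusted over the list alone. RRM2, at −1.80 ± 0.34, did not pass (adjusted p = 0.078, and 0.00827 with replicate number as a term).

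Androgen-induced genes did not separate the arrays labelled DHT parental from those labelled vehicle parental. Their median was −0.05 and their mean 0.07 over 24 genes (adjusted p = 0.645). Over all genes or adjusted over the list alone, 0 were called. SLC45A3 was at −2.22 ± 1.36 and TSC22D1 at 1.39 ± 0.41 (adjusted p = 0.541 and 0.211). With replicate number as a term 5 members rose and 4 fell over all genes, among them TSC22D1 (adjusted p = 0.000334), CENPN (0.0302) and, lower, SLC45A3 (0.000259). Glucocorticoid-induced genes had a median of 0.70 over 17 genes (adjusted p = 0.00276, and adjusted p = 0.33 with an estimated correlation). By either adjustment 1 rose, LCN2 (lipocalin 2), at least 8.49-fold. CDKN1C, at 3.10 ± 0.83, and DDIT4, at 0.62 ± 0.25, did not pass; with replicate number as a term CDKN1C did (adjusted p = 0.00327). ER chaperone and unfolded protein response genes had a median of 0.28 over 23 genes (adjusted p = 3.15e-05), interferon response genes 0.40 over 12 (adjusted p = 0.0229), and cholesterol and fatty acid synthesis genes 0.19 over 20 (adjusted p = 0.0399). Each of these 3 lists had an adjusted p = 0.33 with an estimated correlation, with 0 members called over all genes and 1 adjusted over the list alone. Over all genes, 4 ER, 1 interferon, 3 cholesterol and 6 glucocorticoid-induced genes rose and 1 cholesterol gene fell when replicate number was a term. Named members were DDIT3 at 1.36 ± 0.30, IFI6 at 1.17 ± 0.20 and SREBF1 at 0.66 ± 0.14. Without the vehicle parental array of replicate 1, the glucocorticoid-induced (adjusted p = 0.0676), cholesterol (0.317), ER (0.168) and interferon lists (0.0676) no longer passed. Without the DHT parental array of replicate 2 the glucocorticoid-induced (0.143) and cholesterol lists (0.09) did not pass, and without that of replicate 1 the interferon list did not (0.427). Restricted to probes detected on all 8 arrays, the glucocorticoid-induced (0.12) and cholesterol lists (0.0998) were not called either.

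Other lists did not pass in this comparison. Their medians were −0.72 for androgen-repressed genes (9 measured), −0.91 for androgen metabolism genes (9), −0.26 for polyamine genes (10), 0.06 for p53 target genes (13), −0.05 for glycolysis genes (19), 0.54 for metallothionein genes (3), 0.23 for luminal epithelial genes (13), 0.60 for mesenchymal genes (7), −0.03 for neuroendocrine and neuronal genes (3), −0.03 for steroid receptors and partner factors (13) and 0.16 for common control genes (12). Adjusted p-values ran from 0.122 for mesenchymal genes to 0.995 for glycolysis genes, and the neuroendocrine median differed in sign from its mean of 0.15. The androgen-repressed (adjusted p = 0.03), androgen metabolism (0.022), metallothionein (0.0229) and mesenchymal lists (0.043) passed with replicate number as a term. Basal epithelial genes (1 measured) and blood and endothelial cell markers (2 measured) were too few to test. Some genes stand in more than 1 list, as FKBP5 and SGK1 do for the androgen-induced and glucocorticoid-induced lists and MT1X and MT2A for the glucocorticoid-induced and metallothionein lists.

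**Figure D4:**
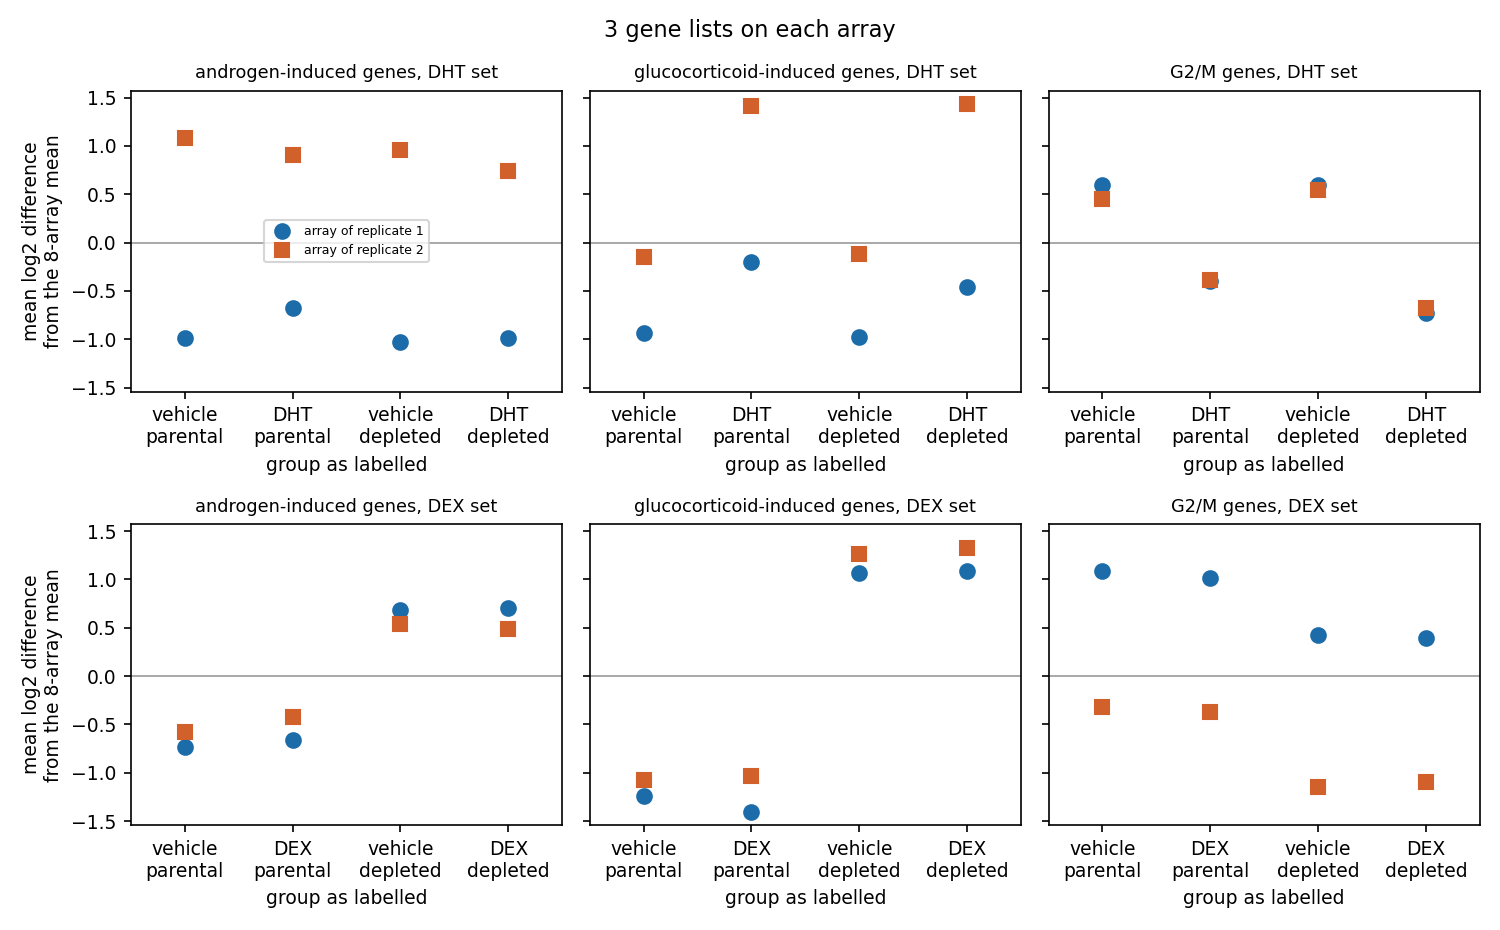
Mean log2 difference of 3 gene lists from their mean over the 8 arrays of the set, on each array, by labelled group (point shape and colour, replicate number; the line at 0 is the set's mean). In the DHT set the androgen-induced list was at −0.98 and 1.08 on the 2 arrays labelled vehicle parental, replicate 1 first.

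The response of FOXA1-depleted cells to DHT was asked of the arrays labelled DHT depleted against those labelled vehicle depleted. ENC1 was higher by 4.82 ± 0.19 (± SE, n = 2 arrays per group; adjusted p = 0.000112), IGFBP3 by 5.23 ± 0.55 and S1PR3 by 4.07 ± 0.43. SLPI (at least 34.2-fold), CA4 (at least 19.9-fold), SCGN (at least 13.5-fold), THBS1 (at least 12.3-fold) and the acyltransferase GLYATL2 (at least 11.4-fold) were not detected on the arrays labelled vehicle depleted. SPON2 fell by 2.57 ± 0.30, HES6 by 2.33 ± 0.34, CDCA5, a regulator of sister chromatid cohesion, by 2.20 ± 0.36, and TFF3 by 2.14 ± 0.35. Undetected on the arrays labelled DHT depleted were AMHR2 (at least 3.98-fold lower), HLA-DMB (at least 3.07-fold), RRM2, a subunit of ribonucleotide reductase (at least 2.59-fold), and the condensin subunit NCAPG (at least 2.43-fold). FOXA1 differed by −1.30 ± 0.11 (adjusted p = 0.00524), again between arrays that share a label of the siRNA.

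By the limma test 84 of 9027 genes were called (37 higher and 47 lower), and 1200 at an unadjusted p under 0.05. The counts of higher and lower genes were 335 and 446 with replicate number as a term. All 84 had groups that did not overlap, as did 43.4% of all genes. The count was 6 and 7 without the vehicle depleted arrays of replicates 1 and 2, and 9 and 26 without the DHT depleted arrays of replicates 1 and 2. Of 23 called and named genes, 4, 3, 3 and 11 passed without these arrays in the same order. ENC1, CA4 and SCGN passed without any 1 of them, while FOXA1 missed without the vehicle depleted array of replicate 1 (adjusted p = 0.0611) or 2 (0.0674) and without the DHT depleted array of replicate 1 (0.0527). Under at least 1 other setting HLA-DMB, HES6, NCAPG, CDCA5, RRM2 and TFF3 did not pass, with adjusted p of 0.0506 to 0.109.

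Cell cycle lists were again lower, here on the arrays labelled DHT depleted. G2/M genes had a median of −1.23 over 25 (adjusted p = 1.65e-22, and 0.0117 with an estimated correlation), with 9 fallen over all genes and 22 adjusted over the list alone. Among them were TOP2A (−2.04 ± 0.17), NUSAP1, a spindle protein (−1.74 ± 0.21), and UBE2C (−1.60 ± 0.17). The G1/S median was −1.17 over 23 (adjusted p = 2.78e-13, and adjusted p = 0.233 with an estimated correlation). It had 3 members fallen over all genes (GINS2 −1.66 ± 0.19, MCM7 −1.26 ± 0.17, and RRM2) and 18 adjusted over the list alone.

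Among hormone lists, androgen-induced genes had a median of −0.27 and a mean of −0.09 over 24 genes, while the list test pointed up (adjusted p = 0.757). By either adjustment 0 were called, while with replicate number as a term 5 rose and 5 fell over all genes. KLK4, a secreted kallikrein, was at 0.62 ± 0.28 and TSC22D1 at 1.32 ± 0.41. Glucocorticoid-induced genes had a median of 0.70 over 17 (adjusted p = 0.003, and adjusted p = 0.342 with an estimated correlation), and LCN2 rose by 2.98 ± 0.28, the 1 member called by either adjustment. Steroid receptors and partner factors had a median of −0.17 over 13 (adjusted p = 0.0297, and 0.286 with an estimated correlation), with 1 called over all genes, FOXA1 itself, and 3 adjusted over the list alone. Interferon response genes had a median of 0.55 over 12 (adjusted p = 0.003, and 0.286 with an estimated correlation) and ER chaperone genes 0.28 over 23 (adjusted p = 0.00515, and 0.541 with an estimated correlation), both with 0 called by either adjustment. The median of cholesterol and fatty acid synthesis genes was 0.34 over 20 (adjusted p = 0.0297, and 0.286 with an estimated correlation), with 0 called over all genes and 1 risen and 1 fallen adjusted over the list alone. For mesenchymal genes it was 1.01 over 7 (adjusted p = 0.0235, and 0.286 with an estimated correlation), with 0 called over all genes and 2 risen adjusted over the list alone. The fibroblast marker S100A4 was at 1.01 ± 0.30 and did not pass.

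Most of these list calls were lost with 1 array left out. That leaves its group with a lone replicate number, so part of the difference between replicate numbers enters the comparison. Between replicate numbers the glucocorticoid-induced list differed by a median of 1.17 in this set. The losses therefore do not show that single arrays were deviant. Without the vehicle depleted array of replicate 1, the glucocorticoid-induced (adjusted p = 0.0597), cholesterol (0.137) and ER lists (0.263) did not pass, and without that of replicate 2 the steroid receptor list did not (0.0854). The cholesterol and interferon lists were also lost without the DHT depleted array of replicate 1, with medians of 0.2421 and 0.2448. Leaving out that of replicate 2 ended the calls of the glucocorticoid-induced (0.276, with the median at −0.07), mesenchymal (0.127) and steroid receptor lists (0.0779). Restricted to probes detected on all 8 arrays, these same 3 lists did not pass (0.113, 0.444 and 0.0669), nor did the mesenchymal list without background correction (0.0698). With replicate number as a term the steroid receptor list was lost (0.0773), while the androgen-repressed (0.0312), androgen metabolism (0.0208), metallothionein (0.0438) and luminal epithelial lists (0.0491) passed. Over all genes 6 glucocorticoid-induced, 4 ER, 2 interferon, 2 cholesterol and 1 mesenchymal gene then rose, and 1 cholesterol gene fell.

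Whether the labelled depletion changed the labelled DHT response was tested as an interaction. The labelled DHT response of G2/M genes was more negative in the cells labelled depleted (median difference between the responses −0.25 over 25 genes, 2 of them above 0; adjusted p = 1.15e-06, and adjusted p = 0.12 with an estimated correlation). That median ran from −0.4388 to −0.2205 as each array was left out in turn. PTTG1, the securin gene, was at −0.96 ± 0.26, NUSAP1 at −0.83 ± 0.30 and TOP2A at −0.74 ± 0.25, none past the threshold. The other 17 lists did not pass, the smallest adjusted p being 0.447. The limma test called 0 of 9027 genes, and 84 at an unadjusted p under 0.05, fewer than the 451 that chance gives for independent arrays. As the fit counts the difference between replicate numbers as spread, that shortfall does not show that the responses are equal. With replicate number as a term 0 genes were called as well. Across genes, the labelled responses of parental and depleted cells correlated at Pearson r = 0.841 (rho 0.707; genes are not independent replicates). In both, 32 genes were higher and 26 lower, and 0 went opposite ways, where independent calls give 0.156 and 0.161.

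The effect of the labelled depletion in the DHT set was compared without and with hormone. FOXA1 differed by 0.05 ± 0.11 between the arrays labelled vehicle depleted and vehicle parental, and by 0.07 ± 0.11 between those labelled DHT depleted and DHT parental, so the arrays labelled depleted held no less FOXA1. The limma test called 0 of 9027 genes in each comparison, with 128 and 154 at an unadjusted p under 0.05. Adding replicate number as a term called 0 in each as well. Of 18 lists, 0 passed on the arrays labelled vehicle (smallest adjusted p 0.531), and only G2/M genes passed on those labelled DHT (median −0.25, 3 of 25 above 0; adjusted p = 6.14e-08, and adjusted p = 0.0871 with an estimated correlation), with 0 members called. On these arrays the androgen-induced list passed with replicate number as a term (median −0.24; adjusted p = 0.00407), again with 0 members called. Changes on arrays labelled vehicle and labelled DHT correlated across genes at r = 0.151, which was 0.0544 without the vehicle parental array and 0.0418 without the DHT parental array of replicate 2, and 0.0765 and 0.0452 without the vehicle depleted and the DHT depleted array of replicate 1.

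The response to DEX was asked of the arrays labelled DEX against those labelled vehicle, and neither SGK1 nor FKBP5 was called. Glucocorticoid-induced genes had a median of 0.04 over 19 genes in cells labelled parental (mean −0.06) and 0.00 in cells labelled depleted, where the mean was 0.04 (adjusted p = 0.983 and 0.966), and 0 members were called by either adjustment. Androgen-induced genes were at 0.07 and −0.05 over 25 genes. FOXA1 was 0.04 ± 0.82 and 0.01 ± 0.82 apart. The limma test called 0 of 10993 genes on the arrays labelled parental, 0 on those labelled depleted and 0 for the interaction. At an unadjusted p under 0.05 there were 71, 64 and 80, where chance gives 550 for independent arrays. As the fit counts the difference between replicate numbers as spread, these low counts do not show that DEX had no effect. Adding replicate number as a term called 0 genes in all 3 as well. Of 19 lists, 0 passed in any of the 3, the smallest adjusted p being 0.394, for ER chaperone genes in parental cells. Simulated responses of 3 on the log2 scale were called in 80 of 100 genes at this number of arrays, and of 1 in 32. The simulation drew genes and arrays independently. With no difference shared by arrays of 1 replicate number, it does not give the power on the real arrays. The labelled responses of parental and depleted cells correlated across genes at r = −0.0148, and at −0.0318 and 0.0167 without the vehicle depleted arrays of replicates 1 and 2, the widest range as each array was left out in turn.

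The effect of FOXA1 depletion without hormone was asked, in the DEX set, of the arrays labelled vehicle depleted against those labelled vehicle parental. SGK1, a kinase gene induced by glucocorticoids, was at 14.43 ± 0.22 against 5.33 ± 0.33 (mean ± SD, n = 2 arrays per group), where it was not detected, and so at least 426-fold higher (adjusted p = 9.89e-06). TIPARP, a mono-ADP-ribosyltransferase, was higher by 6.13 ± 0.21 (± SE; adjusted p = 1.21e-05) and the pepsinogen gene PGC by 6.41 ± 0.77, and RASD1, a Ras-related gene named for its induction by dexamethasone, was at least 110-fold and TLCD4 at least 61.3-fold higher. The alpha-tubulin genes TUBA3E (at least 209-fold), TUBA3C (at least 75.9-fold) and TUBA3D (7.50 ± 0.41) were higher too, and their sequences are so alike that a probe can bind more than 1 of them. Lower were ABCG1, a cholesterol exporter (−1.51 ± 0.27), HGC6.3 (2.82-fold lower), SIGIRR (−1.46 ± 0.27), the transcription factor GATA2 (−1.44 ± 0.23), MT1F (−1.44 ± 0.26), RAB27A (−1.43 ± 0.23), PAQR4 (−1.41 ± 0.29) and HOXC13 (−1.40 ± 0.24). FOXA1 differed by −0.98 ± 0.82 and was not called (adjusted p = 0.592), with the 2 arrays of each label 1.81 and 1.27 apart. With replicate number as a term it was called, at −0.98 ± 0.16 (adjusted p = 0.00139). As each array was left out in turn, its difference ran from −1.885 to −0.07866.

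In limma 378 of 10993 genes were called (324 higher and 54 lower on the arrays labelled vehicle depleted), and 1945 at an unadjusted p under 0.05. The excess of increases was absent with replicate number as a term, where 1108 were higher and 1096 lower. All 378 had groups that did not overlap, as did 47.4% of all genes. The count was 152 and 136 without the vehicle parental arrays of replicates 1 and 2, and 159 and 117 without the vehicle depleted arrays of replicates 1 and 2. Of 31 called and named genes, 18, 15, 16 and 16 passed without these arrays in the same order. The 8 with the largest increases, SGK1 to TIPARP, passed without any 1 of them. Under at least 1 other setting HGC6.3, SIGIRR, MT1F, PAQR4, HOXC13, FOLH1, DNAJB11, DNAJC3, HYOU1 and MT1X did not pass, with adjusted p of 0.0508 to 0.0831.

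Glucocorticoid-induced genes were higher on the arrays labelled vehicle depleted, with a median of 2.23 over 19 genes (adjusted p = 1.13e-12, and 0.0232 with an estimated correlation). Over all genes 8 rose and 1 fell (MT1X), and adjusted over the list alone 14 rose and 2 fell. CEBPD, a transcription factor, was higher by 4.94 ± 0.17 and FKBP5 by 4.61 ± 0.13. Cholesterol and fatty acid synthesis genes had a median of 0.83 over 20 (adjusted p = 1.19e-09, and 0.044 with an estimated correlation), with 7 risen over all genes, and 12 risen and 1 fallen adjusted over the list alone. Among them were the sterol synthesis enzymes NSDHL (2.72 ± 0.13), DHCR7 (1.96 ± 0.20) and SQLE (1.86 ± 0.18). Androgen-induced genes had a median of 0.58 over 25 (adjusted p = 1.08e-06, and 0.044 with an estimated correlation), with 6 risen over all genes and 7 adjusted over the list alone. They included the kinase gene STK39 (2.75 ± 0.24) and the shared SGK1 and FKBP5. ER chaperone and unfolded protein response genes had a median of 0.49 over 22 (adjusted p = 1.59e-06, and 0.044 with an estimated correlation), with 3 risen over all genes and 8 adjusted over the list alone. The 3 were DNAJC3 (1.85 ± 0.32), HYOU1 (1.10 ± 0.20) and DNAJB11 (0.73 ± 0.12). Androgen metabolism genes had a median of 0.69 over 10 (adjusted p = 0.0141, and adjusted p = 0.282 with an estimated correlation), with 3 risen by either adjustment. That call was lost with replicate number as a term (adjusted p = 0.0634). The 3 were SRD5A1, a 5-alpha-reductase (3.51 ± 0.22), HSD17B11 (1.58 ± 0.26) and HSD17B4 (1.20 ± 0.15). A fit with replicate number as a term had 14 glucocorticoid-induced, 13 cholesterol, 12 androgen-induced and 11 ER genes risen over all genes, and 2, 1, 1 and 1 fallen.

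Lower as groups on these arrays were metallothionein genes, which bind zinc and copper, with a median of −0.88 over 6 (adjusted p = 0.00258, and adjusted p = 0.102 with an estimated correlation); MT1F and MT1X (−0.73 ± 0.13) fell over all genes and 3 members adjusted over the list alone. Androgen-repressed genes had a median of −0.87 over 12 (adjusted p = 0.0159, and adjusted p = 0.146 with an estimated correlation), with 2 fallen by either adjustment, the chemokine receptor ACKR3 (−1.19 ± 0.17) and FOLH1, which encodes prostate-specific membrane antigen (−1.05 ± 0.20). Of these lists, 6 androgen-repressed and 3 metallothionein genes fell with replicate number as a term. The androgen-repressed median ran from −1.112 to −0.1502 as each array was left out in turn. The G1/S list (median −0.69 over 24; adjusted p = 0.00258), the G2/M list (−0.80 over 27; 0.0178) and the interferon list (−0.56 over 18; 0.0488) had 0 members called by either adjustment, and 15, 15 and 3 members fallen and 0, 0 and 1 risen over all genes with replicate number as a term. With an estimated correlation they had adjusted p = 0.608, 0.696 and 0.608, and SKP2 was at −0.68 ± 0.19, CCNB1 at −1.12 ± 0.49 and IFIT1 at −1.30 ± 0.45. Without the vehicle parental array of replicate 1, the androgen-repressed (adjusted p = 0.0955), G1/S (0.306) and G2/M lists (0.87) did not pass. The same 3 lists missed without the vehicle depleted array of replicate 2 (0.0777, 0.356 and 0.946, with the G2/M median turned to 0.07). Without the vehicle parental array of replicate 2 or the vehicle depleted array of replicate 1, the androgen metabolism list (0.125 and 0.0678) and the interferon list (0.415 and 0.264) did not pass. The interferon list also missed with offset 50 (0.0542), without the filter (0.121) and on probes detected on all 8 arrays (0.212). Not past the threshold were polyamine genes (median −0.23 over 11, mean 0.06), p53 target genes (−0.07 over 16, mean 0.12), glycolysis genes (−0.09 over 18), luminal epithelial genes (−0.22 over 14), basal epithelial genes (0.06 over 3, mean −0.09), mesenchymal genes (0.20 over 7), neuroendocrine and neuronal genes (−0.15 over 4), steroid receptors and partner factors (−0.26 over 12) and common control genes (0.05 over 12), with adjusted p-values from 0.0826 to 0.979.

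With hormone, the question was asked of the arrays labelled DEX depleted against those labelled DEX parental. SGK1 was at least 443-fold higher, FKBP5 higher by 4.49 ± 0.13, CEBPD by 4.74 ± 0.17, SRD5A1 by 3.40 ± 0.22 and NSDHL by 2.63 ± 0.13 (± SE, n = 2 arrays per group). MSMO1, a sterol synthesis gene, was higher by 2.27 ± 0.23, though its other probes ran from −0.22 to 2.01. FOXA1 differed by −1.02 ± 0.82 (adjusted p = 0.584, and 0.00115 with replicate number as a term). Its difference ran from −1.929 to −0.1013 as each array was left out in turn. The limma test called 369 of 10993 genes (314 higher, 55 lower; 1924 at an unadjusted p under 0.05), and with replicate number as a term 1057 higher and 1122 lower. The count was 147 and 139 without the DEX parental arrays of replicates 1 and 2, and 112 and 93 without the DEX depleted ones. All 369 had groups that did not overlap, as did 46.9% of all genes. Of 12 called and named genes 8 passed without each of these arrays, while HSD17B4, HSD17B11, MT1F and MT1X did not pass when any 1 of them was left out, and also missed under at least 1 other setting (adjusted p of 0.0506 to 0.0972). Across genes this effect correlated with that on the arrays labelled vehicle at r = 0.897 (rho 0.766), with 281 genes higher and 32 lower in both, where independent calls give 9.25 and 0.27.

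Gene lists were tested on these arrays as well. The medians were 2.33 for glucocorticoid-induced genes (adjusted p = 4.32e-14, and 0.0189 with an estimated correlation; 10 risen and 1 fallen, and 14 and 2 adjusted over the list alone), 0.85 for cholesterol genes (5.43e-10; 6 risen, and 12 with 1 fallen adjusted over the list alone), 0.45 for androgen-induced genes (2.9e-05; 6 risen, and 7 adjusted over the list alone) and 0.48 for ER chaperone genes (2.9e-05; 0 called, and 9 risen adjusted over the list alone). With an estimated correlation the last 3 had adjusted p = 0.055, 0.0671 and 0.055. Metallothionein genes (−0.91; adjusted p = 0.00215; 2 fallen, and 4 adjusted over the list alone), androgen-repressed genes (−1.02; 0.0112; 0 called, and 3 adjusted over the list alone), androgen metabolism genes (0.64; 0.0139; 3 risen by either adjustment) and G1/S genes (−0.61; 0.0124; 0 called by either adjustment) passed as well. With an estimated correlation they had adjusted p = 0.0926, 0.118, 0.292 and 0.663. Without the DEX parental array of replicate 1 the androgen-repressed (0.0626) and G1/S lists (0.667) did not pass, nor the androgen metabolism list without that of replicate 2 (0.0855), nor the G1/S list without the DEX depleted array of replicate 2 (0.375). The call of the androgen metabolism list was also lost with replicate number as a term (0.061). Over all genes 9 androgen-repressed, 14 G1/S and 4 metallothionein genes then fell, 12 ER genes rose and 1 fell, 8 androgen-induced genes rose and 1 fell, and 12 cholesterol and 14 glucocorticoid-induced genes rose with 1 and 2 fallen. Without the filter the androgen metabolism list missed, with its median at −0.02 (0.0529). G2/M genes, with a median of −0.63, did not pass (adjusted p = 0.0532), but did with replicate number as a term (1.89e-06; 14 fallen).

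The sets were compared only by correlating changes across the 8794 genes tested in both, and no test was made between them. The labelled vehicle depletion effects of the sets correlated at r = −0.00303. That value was −0.268 and 0.282 without the DHT-set vehicle parental arrays of replicates 1 and 2, and 0.259 and −0.247 without the vehicle depleted ones. The labelled DHT and DEX responses correlated at 0.0728 in cells labelled parental. Without the DEX-set vehicle parental arrays of replicates 1 and 2 the correlation was −0.5185 and 0.61, and without the DEX parental ones 0.587 and −0.575; without the DHT-set vehicle parental array of replicate 1 it was 0.0443. In cells labelled depleted it was −0.0276, with −0.5095 and 0.529 without the vehicle depleted arrays of the DEX set and 0.514 and −0.534 without the DEX depleted ones. Leaving out 1 array lets part of the difference between replicate numbers into its comparison. For the DEX set that difference correlated with the labelled DHT effect at 0.758, so such ranges do not reflect sampling alone. The labelled depletion effect of the DEX set correlated with the labelled DHT response of parental cells at 0.244, with 0 genes called the same way in both, where independent calls give 1.10 higher and 0.187 lower. It was 0.06445, 0.369, 0.4435 and −0.0481 without the vehicle parental and DHT parental arrays of the DHT set, and −0.053, 0.484, 0.428 and −0.0129 without the vehicle parental and vehicle depleted arrays of the DEX set, replicate 1 first in each pair. For the labelled depletion effect of the DHT set against the labelled DEX response it was 0.022, and it was −0.0239 and 0.0554 without the DHT-set vehicle parental arrays of replicates 1 and 2, 0.012 without the vehicle depleted array of replicate 1, and 0.00265 and 0.00268 without the DEX-set vehicle parental and DEX parental arrays of replicate 2.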

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

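The test below was planned. In the DHT set the labelled depletion changed the labelled DHT response of G2/M genes by a median of −0.247 on the log2 scale over 25 genes (adjusted p = 1.15e-06 for the interaction, and adjusted p = 0.12 with an estimated correlation), which marked it as a difference between groups. Of its members 2 of 25 lay above 0, and limma called 0 genes. As each array was left out in turn, its median ran from −0.4388 to −0.2205. The list was lower on the arrays labelled DHT depleted than on those labelled DHT parental (median −0.25). That difference is a part of the interaction, on the same arrays, and no separate observation. FOXA1 differed by 0.07 ± 0.11 between these arrays, so the direction rests on labels that FOXA1 contradicts. No technical or biological explanation was tested for it.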

How the results depend on the processing

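Comparisons with 0 called genes kept 0 under all alternatives run, and the counts of called genes moved. Leaving out 1 array gave 4 to 20 genes for the labelled DHT response of parental cells (69), 6 to 26 for that of depleted cells (84), 117 to 159 for the labelled vehicle depletion of the DEX set (378) and 93 to 147 for that on arrays labelled DEX (369). Fitting only the arrays compared gave 20, 25, 200 and 161, and both leave fewer arrays to estimate the spread. A filter on detection on all 8 arrays gave 45 and 45 for the DHT responses, with fewer genes tested. With replicate number as a term (replicate block) the counts were 749, 781, 2204 and 2179, as that term takes out the large difference between replicate numbers; FOXA1 was then called for the labelled depletion of the DEX set, at −0.98 and −1.02. Of the named genes not called in these 4 comparisons (16, 19, 12 and 11), 11, 14, 9 and 11 were called with that term, and 0 calls were lost. All other alternatives gave 55 to 82, 70 to 105, 299 to 557 and 285 to 534. The correlation across genes of the DHT responses was 0.8686 without background correction, 0.7067 without the filter and 0.7074 to 0.767 with 1 array left out. That of the DEX responses was −0.03545 without background correction and −0.03176 to 0.01668 with 1 array left out. For the depletion effects of the DEX set it was 0.9256 with offset 50, 0.9363 without background correction, 0.8675 from the authors' values, 0.8124 without the filter and 0.7873 to 0.8421 with 1 array left out, and for those of the DHT set 0.07959 without the filter and 0.04176 to 0.1479. With 1 array left out, the depletion effects of the sets correlated at −0.268 to 0.2822, the DHT and DEX responses at −0.5754 to 0.61 (parental) and −0.5342 to 0.5294 (depleted), the DEX-set depletion and DHT response at −0.05301 to 0.484, and the DHT-set depletion and DEX response at −0.02391 to 0.05539, the last being 0.0479 without background correction. FOXA1 turned in sign only where it was not called: DHT interaction −0.03626 to 0.0809, vehicle depletion of the DHT set −0.006406 to 0.1108, DEX response −0.5939 to 0.6753 (parental) and −0.9071 to 0.921 (depleted, and −0.0209 under median scaling), and DEX interaction −0.9479 to 0.8803. The G2/M median for the vehicle depletion of the DEX set ran from −1.64 to 0.07374. Of 34 list calls, 34 held under median scaling, 34 with the authors' values, 28 with detection on all 8 arrays, 31 with the replicate block and 7 with an estimated correlation. The 3 that the block ended were steroid receptors for the DHT response of depleted cells (adjusted p = 0.0773) and androgen metabolism for both depletion effects of the DEX set (0.0634 and 0.061). Leaving out 1 array also leaves its group with a lone replicate number, so part of the difference between replicate numbers enters that comparison. Besides this and the arrays and genes removed by construction, the cause was not tested. For 28 named results, no value could be had under detection on all 8 arrays, since the gene did not pass it. Low signal over background limits undetected genes to bounds, as for SLPI and SGK1.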

Other observations

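All tests in this part were chosen only after the result was seen. Hormone-regulated genes separated arrays of the same label. In the DHT set, arrays of replicate 2 differed from arrays of replicate 1 in 1200 of 9027 genes (575 higher, 625 lower) when replicate number was a term beside the labelled group. Androgen-induced genes had a median difference of 1.59 over 24 genes, 22 of them higher (adjusted p = 1.94e-27, and adjusted p = 0.105 with an estimated correlation): FKBP5 was higher by 4.58, the prostate gene PMEPA1 by 3.20, ELL2 by 2.71, SLC45A3 by 2.58, NDRG1 by 1.72, KLK3, which encodes prostate-specific antigen, by 1.62 and TMPRSS2 by 1.60. Androgen-repressed genes had a median of −1.49 over 9, with 8 lower and 1 higher (adjusted p = 9.78e-07, and adjusted p = 0.105 with an estimated correlation), and glucocorticoid-induced genes 1.17 over 17, with 10 higher and 2 lower (3.67e-06, and adjusted p = 0.113 with an estimated correlation).

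Cell cycle genes separated the replicate numbers in the DEX set, where 2672 of 10993 genes differed (1231 higher and 1441 lower on arrays of replicate 2). G2/M genes had a median of −1.56 with 26 of 27 lower (adjusted p = 1.53e-22, and adjusted p = 0.0547 with an estimated correlation), and G1/S genes −0.93 with 20 of 24 lower and 1 higher (1.71e-14, and adjusted p = 0.081 with an estimated correlation). FOXA1 was lower on arrays of replicate 2 by −1.525 ± 0.113. Androgen-induced genes had a median of 0.07 over 25 in this set (adjusted p = 0.736).

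FOXA1 was lower on the arrays labelled DHT in the DHT set. A candidate explanation is that arrays carry the labels of other arrays. The labelled DHT effect of the DHT set then should resemble the difference between replicate numbers in the DEX set, where FOXA1 differs by number, and the 2 correlated across 8794 genes at r = 0.758, against 0.131 with the replicate number difference of the DHT set itself. That the labels are correct, FOXA1 was depleted as labelled and DHT lowers it is argued against by FOXA1 itself, which differed by 0.05 ± 0.11 and 0.07 ± 0.11 between arrays labelled depleted and parental. That the labels are correct, the siRNA had no effect in this set and DHT lowers FOXA1 is not settled. It predicts a rise of androgen-induced genes on the arrays labelled DHT parental, which was not seen. With replicate number as a term that list had a median of −0.05 there, with 5 members higher and 4 lower. Androgen-repressed genes, which it predicts to be lower, had a median of −0.72 over 9, with 4 lower and 2 higher. The androgen-induced list followed the replicate number instead (median 1.59, 22 of 24 genes higher). Whether a batch of cell culture gives such a difference was not tested. Which array belongs to which condition was not worked out.

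Glucocorticoid-induced genes were higher on the arrays labelled depleted in the DEX set. The same candidate explanation predicts that this labelled effect resembles the replicate number difference of the DHT set, where androgen-induced genes follow the number, and the correlation across genes was 0.557, against 0.125 with the replicate number difference of the DEX set itself. If the labels were correct and loss of FOXA1 raised these genes, they should also be higher on the arrays of replicate 2, which held less FOXA1. With replicate number as a term, which keeps the difference by number out of the call, 14 of 19 members were called higher, by a median of 2.51 (0.776 to 9.09). Their median difference between replicate numbers was −0.029 (SD 0.38, −0.449 to 0.646), with 4 called higher and 0 lower. For 14 of 14 it was smaller than the labelled difference, which is partly built in, as they were picked for that difference. Over all 19 measured members the median difference by number was 0.002, with 6 called higher and 0 lower. Such small medians by number argue against that explanation.

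The most similar arrays shared a replicate number in both sets, along with the labelled hormone in the DHT set and the labelled depletion in the DEX set. A hybridization batch blind to gene identity would leave the replicate number difference of each set unrelated to the labelled effects of the other set. Within bins of mean expression, the replicate number difference of the DEX set correlated with the labelled DHT effect at 0.758, and that of the DHT set with the labelled depletion effect of the DEX set at 0.556, which argues against it. Batches of cell culture were not tested and stay open beside arrays carrying the labels of other arrays. In each set 2 of the 35 splits of the 8 arrays into 4 and 4 called as many genes as the split by replicate number (350 in the DHT set and 993 in the DEX set). The other was a labelled contrast, of hormone in the DHT set (970) and of depletion in the DEX set (2319), and the splits that follow no label called 0. Over both sets, 4 of the 1225 pairs of splits called as many genes in each set. The split by number was examined after the arrays were seen to share it, so this count cannot exclude chance. The split by replicate number points to a structure of the samples that the labelled groups do not describe.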
